A study of Mus musculus with 50 samples.

How the data were processed

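RNA from mouse airways was hybridised on 50 spotted arrays with 2 channels each. Per the labels, the first channel held a reference and the second held the sample. The samples formed 10 groups of 5 arrays, 5 groups from tracheal perfusate and 5 from whole lung. In each tissue, 3 groups carried IL-13 and were Stat6+/-, Stat6-/- or Stat6-/- with the mark Epi+, and the others had received ovalbumin (OVA) or phosphate-buffered saline (PBS). Per the labels' descriptions, perfusate RNA went through 1 round of amplification. The labels of 3 perfusate arrays hybridised against reference preparation 1.3 do not state the amplification. Replicate numbers were taken from the labels' titles. Nothing in the labels says that the arrays came from separate animals, so p-values measure only the spread between these samples, which may be technical.

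The deposited values are log2 ratios, 1 per spot, on a platform of 19152 spots for 40 arrays and on another of 18240 spots for the 10 whole lung OVA and PBS arrays. Raised to the power of 2, 100% of them were linear ratios of 3 decimals within a tolerance of 2e-04, with a lowest ratio of 0.001. Scanner, background correction, filtering and normalization are not given in the sources used here. The array medians ranged from -0.96 to 0.30, so the deposited values had not been centred. The sources do not state the direction of the ratio. It was taken as sample over reference, which is likely because Il13 was higher by 2.72 ± 0.21 in perfusate of IL-13 Stat6-/- animals than in PBS perfusate. No spot intensities were used, so dye bias that depends on intensity could not be removed, and no probe was filtered on signal over background. Arrays held between 15693 and 18655 spots with a value, and the number of arrays limits the precision.

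The design had been fixed for normalized values, with centring of each array on its median as an alternative. Once the deposited medians were seen to differ, and before any comparison was run, centring became the main setting and the values as deposited became an added alternative. Centring gave more calls in all 11 comparisons. The counts without it were 128, 17, 0, 15 and 4 in perfusate, 284, 6, 77 and 36 in whole lung, and 373 and 5 for the tissue differences, in the order in which the comparisons are reported. The group means of the removed array medians differed by more than 0.1 in 8 of the comparisons. The shifts were 0.12 for Stat6+/- against Stat6-/- and -0.20 for Stat6-/- against PBS in perfusate. In whole lung they were -0.37 for Stat6+/- against Stat6-/-, -0.16 for Epi+ against Stat6-/-, -0.21 for Stat6+/- against Epi+ and -0.17 for OVA against PBS. They were 0.49 and 0.18 for the tissue differences. All log2 differences are relative to these shifts.

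Spots of 1 accession were averaged, which left 18272 and 18057 probes. Over 717 accessions with 2 spots the median correlation of the spots across arrays was 0.490. Gene symbols came from the platform annotation, updated through gene identifiers of the RefSeq table of assembly GRCm38 (patch 6). On the larger platform 15418 spots had 1 symbol, 7 had several and 3727 were unlisted. On the smaller platform these numbers were 14857, 6 and 3377. Unlisted spots and those with several symbols were tested but not named. Chil3 and Chil4 had no probe. Probes for close paralogs, such as Clca1 and Clca3b, Hspa1a and Hspa1b, or Rnase2a and its relatives, may share signal.

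Linear models were fitted by exact least squares for each pattern of missing values, with limma 3.58.1 moderation of the variances in R 4.3.3 and Benjamini-Hochberg adjustment over all probes of a comparison. A probe was tested where at least 3 arrays of every group in the fit had a value, and called at an adjusted p under 0.05. The perfusate fit held 25 arrays and a block for the 5 reference preparations, each of which held 1 array of every group. The whole lung IL-13 fit held 15 arrays and a block for reference pools 3 and 4. The whole lung OVA and PBS fit held 10 arrays against 1 pool. The preparation carried 45.0% of the within-group variance in perfusate, on 20% of the degrees of freedom, and 34.5% in whole lung, on 8.33%. The tissue differences were interaction terms in a fit of the 40 arrays of the larger platform. Tables of the 2 platforms were centred separately and no level was tested across them.

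Before the data were examined, 30 gene lists were fixed for airway and lung cell types, immune cells, IL-13 responses, mucus, transport, metabolism, stress and sex-linked genes. Each was tested with cameraPR at a preset inter-gene correlation of 0.01. A second test used camera with the correlation estimated from the data, on probes with a value on every array of the fit. It could hold fewer members of a list, and the numbers of measured genes below are those of the first test. Of 270 list tests in the 9 comparisons within a tissue, 102 passed with the preset and 34 with the estimated correlation. Member calls are given over all probes and adjusted over the list alone. The set of named genes followed a rule fixed beforehand. The text below gives only part of this set, so the genes it gives are a selection. Counts of named genes refer to the whole set. The set held the 12 largest rises and 8 largest falls among called probes with 1 symbol, complete values and non-overlapping groups, then up to 4 called members per list by size, then Stat6, Il13, Clca1, Muc5ac, Chil3, Arg1, Ccl11, Scgb1a1 and Foxj1 whatever their result. A gene with several probes was given by the probe with the most values.

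Alternatives fixed beforehand were scaling and quantile normalization, other filters on missing values, a robust variance model, array weights, each array left out in turn, no reference block, only the groups compared, fits within whole lung reference pools, and the replicate number as a block. Alternatives chosen after seeing the data were the values as deposited, spots tested on their own, probes with 1 symbol only, scaling and quantile normalization for the gene lists, the omission of reference preparation 1.3, probes for the Epi+ slopes picked without the controls of the Epi+ side, and a covariate for, or omission of, the arrays with low Y-linked signal. The procedure was tested on simulated data with 200 changed probes, 100 per size. At a log2 change of 1 it recovered 61% in perfusate Stat6+/- against Stat6-/- (16873 probes), 20% in the same whole lung comparison (16096 probes), 6% in whole lung OVA against PBS (17047 probes) and 15% in the tissue difference (15370 probes). At a log2 change of 2 it recovered 89%, 58%, 55% and 67%. Between 2 and 10 unchanged probes were called. The simulated noise was independent between probes, so these numbers leave out error that the probes of an array share. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.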

Results

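The series compared gene expression in 2 airway preparations of mice, RNA flushed from the trachea (tracheal perfusate, 25 arrays) and RNA of the whole lung (25 arrays), each measured as a log2 ratio to a reference that differed between sets of arrays. IL-13 is a cytokine of allergic inflammation that signals through the transcription factor Stat6. In each tissue, 5 arrays came from IL-13 animals with a working Stat6 allele (Stat6+/-), 5 from IL-13 animals without it (Stat6-/-), 5 from IL-13 Stat6-/- animals marked Epi+, 5 from animals given ovalbumin, an allergen, and 5 from animals given saline (PBS). In mouse lines of this name Epi+ stands for a transgene that restores Stat6 in airway epithelial cells; the labels give only the mark. By its title, the series concerned changes that IL-13 causes directly in epithelial cells of the airway. Arrays had 15693 to 18655 spots with a value. Differences below are log2 differences with the standard error of the limma fit, over 5 arrays per group unless a number is given, and adjusted p-values are limma's with Benjamini-Hochberg adjustment.

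The genes that the design alters were read first. The Stat6 probe had about the same level in Stat6+/- and Stat6-/- arrays, with a difference of -0.10 ± 0.14 in perfusate (adjusted p = 0.851) and -0.19 ± 0.28 in whole lung (adjusted p = 0.766). Between Epi+ and Stat6-/- arrays it differed by -0.10 ± 0.14 in perfusate and 0.20 ± 0.28 in whole lung, neither of which passed. Where the probe lies relative to the disruption is not given in the sources used here. Whether these levels test the genotype labels or the mark Epi+ therefore stays open. Il13 stood at 2.76 ± 0.55 (SD, n = 5) in Stat6-/- perfusate against 0.04 ± 0.34 in PBS perfusate, and at 5.34 ± 0.82, 5.18 ± 0.43 and 5.54 ± 0.56 in whole lung of Stat6+/-, Stat6-/- and Epi+ animals. In 3 perfusate arrays (Stat6-/- replicates 10, 11 and 12) and 2 whole lung arrays (Stat6-/- replicates 1 and 2) 1 of 2 spots of the Y-linked gene Eif2s3y lay at -1.93 or lower, against -0.71 or higher on the other arrays of the same platform. The other spot of Eif2s3y stood at 0.52, 0.17 and 0.03 on the 3 perfusate arrays, at -3.63 on the first whole lung array and had no value on the second. Uty, also Y-linked, was -2.10, -0.95 and -0.93 on these perfusate arrays, against -0.98 on Stat6+/- replicate 4, and -3.66 and -4.35 on these whole lung arrays. Xist, which is expressed from an inactive X chromosome, lay between -0.33 and 0.91 on these 3 perfusate arrays against -5.70 to -1.36 on the other perfusate arrays. In whole lung it was 7.35 on Stat6-/- replicate 1, had no value on replicate 2, and lay between -3.15 and 2.07 on the other arrays with a value. The sex of the animals is not given in the sources used here, and each comparison with a Stat6-/- group was repeated with these arrays marked by a covariate and without them.

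**Figure D1:**
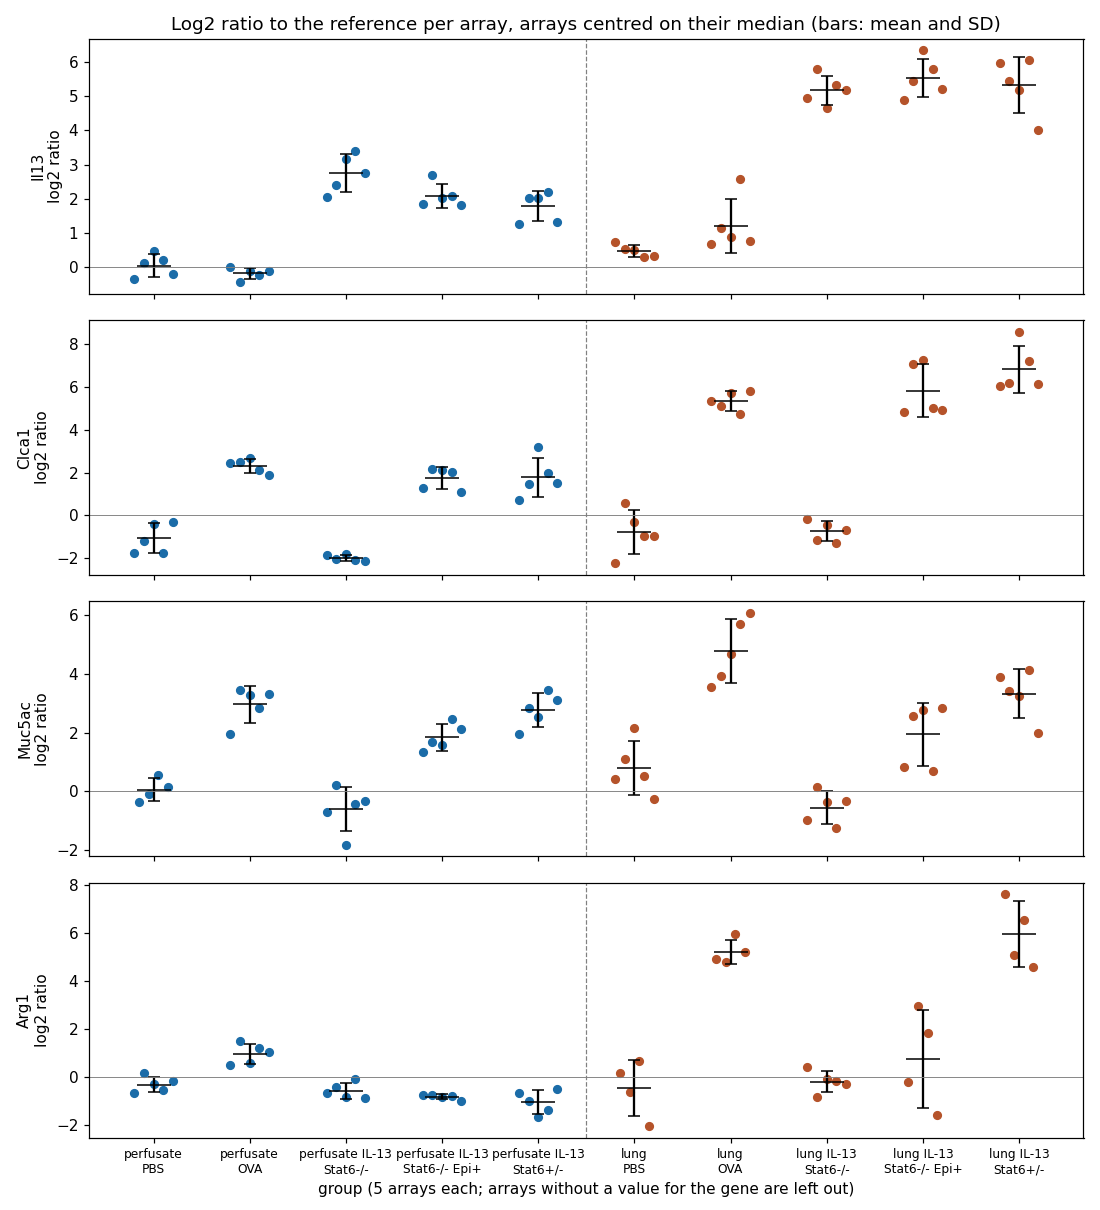
Log2 ratio to the reference of Il13, Clca1, Muc5ac and Arg1 on each array (points), by group (x axis), with the mean and SD of the group; perfusate is blue and whole lung is orange. Clca1 averaged -1.99 in Stat6-/- perfusate against 1.78 with Stat6+/- and 1.76 with Epi+, while Arg1 averaged 5.93 in Stat6+/- whole lung against 0.73 with Epi+.

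The first comparison set Stat6+/- against Stat6-/- tracheal perfusate of IL-13 animals. No group is labelled with these genotypes without IL-13. A genotype difference present without IL-13 therefore cannot be told apart from a changed IL-13 response, here or in whole lung. Genes of mucous cells were higher in Stat6+/- than in Stat6-/- perfusate. Clca1, a secreted product of goblet cells, rose by 3.77 ± 0.31 (13.6-fold, adjusted p = 1.18e-06), the gel-forming mucin Muc5ac by 3.38 ± 0.29, the trefoil peptide Tff1 by 2.84 ± 0.42 and Spdef, a transcription factor of goblet cell differentiation, by 1.05 ± 0.23. Enzymes that detoxify foreign compounds were lower, with Gsta2 at -1.65 ± 0.24, the aldehyde oxidases Aox1 at -1.62 ± 0.25 and Aox3 at -1.47 ± 0.15, and Fmo2 at -1.56 ± 0.25. In all, 529 of 16873 probes passed, 188 higher and 341 lower.

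Of 22 measured genes of mucous cells and mucus secretion 7 rose and none fell, and 11 passed when adjusted over the list alone (list adjusted p = 7.65e-15, and adjusted p = 0.000301 with an estimated correlation). Of 30 genes of xenobiotic and glutathione metabolism 10 fell and none rose, 14 adjusted over the list alone (adjusted p = 6.31e-17, and 0.00272 with an estimated correlation). Of 26 genes of the secretory machinery and stress response of the endoplasmic reticulum 3 rose, 7 adjusted over the list alone, namely Manf at 0.77 ± 0.19, Dnajb9 at 0.76 ± 0.20 and Ddit3 at 0.68 ± 0.17 for the first count (adjusted p = 1.72e-05, and 0.0411 with an estimated correlation). Of 19 genes of ciliated cells 4 rose, 8 adjusted over the list alone, including Spag16 at 1.17 ± 0.27 and Ift172, a part of the transport system in cilia, at 0.91 ± 0.14. That list had an adjusted p = 1.53e-06, and adjusted p = 0.0582 with an estimated correlation. Of 17 genes of club and other secretory cells 3 fell, 4 adjusted over the list alone, with Cckar at -2.05 ± 0.29 and Pon1 at -1.75 ± 0.19, and the list's adjusted p of 8.41e-09 became adjusted p = 0.0871 with an estimated correlation. Of 22 genes of airway host defence and the acute phase 3 fell, 5 adjusted over the list alone. They were surfactant protein Sftpa1 at -2.55 ± 0.25, the haemoglobin-binding protein Hp at -2.53 ± 0.19 and complement factor Cfb at -1.20 ± 0.27 (adjusted p = 0.00167, and adjusted p = 0.399 with an estimated correlation). Of 19 genes of alternative activation by IL-4 and IL-13, 2 rose, 4 adjusted over the list alone (adjusted p = 0.0454, and adjusted p = 0.0582 with an estimated correlation). No member of the lists of 17 T cell and 15 B and plasma cell genes passed, also not adjusted over the list alone, and the list medians were 0.39 and 0.44 (adjusted p = 0.00345 and 0.0138, and adjusted p = 0.344 and 0.399 with an estimated correlation).

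Ion transporters moved both ways. The anion exchanger Slc26a4 rose by 1.99 ± 0.28 and carbonic anhydrase Car2 by 1.15 ± 0.22, while the sodium channel subunits Scnn1b and Scnn1g were lower at -1.58 ± 0.32 and -1.56 ± 0.32. Among enzymes of eicosanoid metabolism, Pla2g10 rose by 2.01 ± 0.37, the prostaglandin D synthase Hpgds by 1.76 ± 0.30 and the lipoxygenase Alox15 by 1.20 ± 0.18. The chemokines Cxcl1 and Ccl19 were lower at -2.46 ± 0.53 and -0.87 ± 0.21, and Ccl20 fell by 2.00 ± 0.24. Other large rises were the protease inhibitor Spink1 at 3.47 ± 0.43, Clca3b at 2.80 ± 0.27, the calcium pump Atp2a1 at 2.66 ± 0.27, Nadsyn1 at 2.47 ± 0.27 and the actin-severing protein Scin at 2.02 ± 0.23. Akr1c18, a steroid-metabolising enzyme, had the largest named fall at -2.79 ± 0.21. Il13 itself was lower at -0.99 ± 0.21 (adjusted p = 0.012). Arg1, Ccl11, Scgb1a1 and Foxj1 did not pass, at -0.47 ± 0.22, 0.30 ± 0.49, -0.28 ± 0.22 and 0.69 ± 0.26. Without centring of the arrays 128 probes passed, 58 higher and 70 lower, leaving out Stat6+/- replicate 8 gave 347, array weights 989, no reference block 270 and a fit of only the 2 groups 69. With the low Y-linked arrays marked by a covariate 163 passed, and 175 without them.

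The second comparison asked how much of this was present when Epi+ was added to Stat6-/- animals. Perfusate of Epi+ animals again held more transcripts of mucous cells than Stat6-/- perfusate. Clca1 rose by 3.74 ± 0.31 (13.4-fold, adjusted p = 3.92e-06), Spink1 by 2.96 ± 0.43, Tff1 by 2.64 ± 0.42, Muc5ac by 2.44 ± 0.29 and Slc26a4 by 2.01 ± 0.28. The neutrophil chemokine Cxcl1 was lower at -3.37 ± 0.53, Sftpa1 at -1.88 ± 0.25, Ccl20 at -1.87 ± 0.24, Cfb at -1.78 ± 0.27 and Hp at -1.32 ± 0.19. In all 82 of 16873 probes passed, 25 higher and 57 lower.

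Of 22 mucous cell genes 3 rose, 5 adjusted over the list alone (adjusted p = 7.67e-12, and 0.00245 with an estimated correlation). Of 19 ciliated cell genes Ccdc39 rose, by 0.93 ± 0.20, and 8 did when adjusted over the list alone (adjusted p = 1.39e-10, and 0.0188 with an estimated correlation). Ccdc39 averaged 0.17 with Epi+ and -0.76 in Stat6-/- perfusate, against 0.42 in PBS perfusate, so its mean with Epi+ was not above that of PBS. Of 26 chemokines 2 fell, 6 adjusted over the list alone (adjusted p = 7.86e-05, and adjusted p = 0.142 with an estimated correlation). Of 30 xenobiotic metabolism genes Aox3 fell by 0.73 ± 0.15, and 7 were lower when adjusted over the list alone (adjusted p = 0.000111, and adjusted p = 0.107 with an estimated correlation). Of 22 host defence genes 3 fell, and adjusted over the list alone 4 were lower and 1 higher (adjusted p = 7.86e-05, and adjusted p = 0.137 with an estimated correlation). Of 17 club cell genes 2 fell, 3 adjusted over the list alone (adjusted p = 0.00226, and adjusted p = 0.314 with an estimated correlation). Atp2a1 rose by 2.60 ± 0.27, Nadsyn1 by 2.56 ± 0.27, Scin by 2.12 ± 0.23, the tight junction protein Cldn2 by 1.66 ± 0.23, tissue plasminogen activator Plat by 1.27 ± 0.21, Car2 by 1.20 ± 0.22 and Alox15 by 1.06 ± 0.18. Akr1c18 was lower at -1.71 ± 0.21, Pon1 at -0.96 ± 0.19 and the endotoxin receptor Cd14 at -1.12 ± 0.21. Il13 did not pass at -0.67 ± 0.21 (adjusted p = 0.261). Without centring 17 probes passed, 11 higher and 6 lower, and the counts without Epi+ replicates 17, 19 or 20 were 42, 50 and 42, and without Stat6-/- replicates 10, 13 or 14 they were 54, 47 and 46. With the low Y-linked arrays marked by a covariate 22 passed, 13 higher and 9 lower, and without them 34, 20 higher and 14 lower, while 35 passed without reference preparation 1.3, 170 with array weights, 50 after scaling, 51 after quantile normalization, 31 without a reference block and 1 in a fit of only the 2 groups.

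Set against each other directly, Stat6+/- and Epi+ perfusate differed at 4 of 16873 probes, and 1184 had an unadjusted p under 0.05. Clca3b, a relative of Clca1 that may share signal with it, was higher in Stat6+/- by 1.86 ± 0.27, the heat shock protein Dnajb1 was higher by 1.38 ± 0.23, and Hp was lower at -1.20 ± 0.19, while the other called probe, which was higher, has no listed gene. Clca1 differed by 0.02 ± 0.31 and Muc5ac by 0.94 ± 0.29 (adjusted p = 0.391), neither of which passed. Of 30 xenobiotic metabolism genes none passed over all probes and 8 were lower in Stat6+/- when adjusted over the list alone (adjusted p = 9.35e-12, and 0.0193 with an estimated correlation). Of 15 genes of MHC class II antigen presentation none passed, also not adjusted over the list alone, with a list median of 0.70 (adjusted p = 5.92e-07, and adjusted p = 0.247 with an estimated correlation). Without centring, after scaling or quantile normalization, or in a fit of only the 2 groups, 0 probes passed, and 2 without a reference block, with at least 2 arrays per group, with a robust variance model or with probes of 1 symbol. Probes with a value on every array gave 7, array weights gave 261, 147 higher and 114 lower, and single arrays left out gave between 0 and 18. The count was 18 without Stat6+/- replicate 5, 15 without replicate 4 and 0 without replicates 6 or 8, while without Epi+ replicate 18 it was 1 and without replicates 16, 17, 19 or 20 it was 0.

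Over the 529 probes called in perfusate for Stat6+/- against Stat6-/-, the Epi+ differences had a slope of 0.562 on the Stat6+/- differences (jackknife SE 0.10). The slope was computed with separate Stat6-/- arrays for each side and averaged over 20 such splits. Over the 779 probes called for the same genotypes in whole lung, described below, this slope was 0.228 (SE 0.0729). The slopes differed by 0.334 with a standard error of 0.124. All Stat6-/- arrays had taken part in calling these probes, so the sides were not fully separate. With as many probes picked in each split without the Stat6-/- arrays of the Epi+ side, which was tried after the data were seen, the slopes fell to 0.352 (range over splits 0.246 to 0.473) and 0.144 (0.00603 to 0.215). No standard error was computed for the difference between these lower slopes. In perfusate 23 probes rose and 55 fell in both comparisons, where independent lists would share 0.279 and 1.15. In whole lung 12 rose in both, against 0.388. These counts share the Stat6-/- arrays. Across probes the correlation of the differences was 0.566 in perfusate, against 0.498 in 20 simulations of unchanged groups against the same Stat6-/- arrays, with covariances of 0.0980 and 0.0751. In whole lung it was 0.344 against 0.467 simulated, with covariances of 0.171 and 0.183, so correlations across all probes were not above those that shared controls give there. Genes are not independent replicates.

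**Figure D2:**
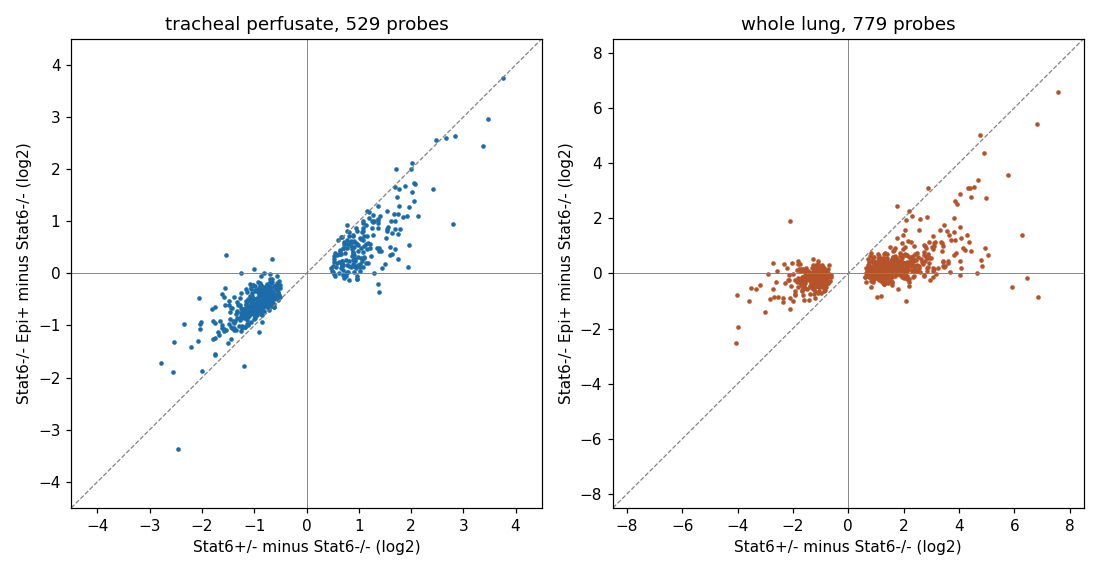
Epi+ minus Stat6-/- differences (y axis, log2) against Stat6+/- minus Stat6-/- differences (x axis, log2) for the 529 perfusate probes and the 779 whole lung probes called in the latter comparison; the dashed line marks equal differences. Both axes share the Stat6-/- arrays, so points lie closer to the line than with separate controls, for which the slopes were 0.562 and 0.228, or 0.352 and 0.144 over probes picked without the controls of the Epi+ side.

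Ovalbumin against PBS in perfusate asked what allergen exposure changes in the same preparation. Clca1 rose by 3.39 ± 0.31 (10.5-fold, adjusted p = 1.98e-05), Muc5ac by 2.81 ± 0.32 (4 PBS arrays) and the acute phase protein Saa3 by 3.10 ± 0.59. Other called genes that rose were the mast cell protease Mcpt2 by 1.55 ± 0.23, the macrophage-secreted protein Cd5l by 1.79 ± 0.27, the eosinophil-associated ribonuclease Rnase2a by 1.88 ± 0.31 and Arg1, an enzyme of alternatively activated macrophages, by 1.28 ± 0.22. The matricellular protein Ccn2 was lower at -1.68 ± 0.29, Fmo1 at -1.15 ± 0.20 and Hp at -0.95 ± 0.19. In all 40 of 16873 probes passed, 29 higher and 11 lower.

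Of 22 mucous cell genes 2 rose, 9 adjusted over the list alone (adjusted p = 9.97e-20, and 1.33e-05 with an estimated correlation). Of 28 cell cycle genes none passed over all probes and 10 were higher when adjusted over the list alone (adjusted p = 2.02e-10, and 0.0372 with an estimated correlation). Of 19 genes of alternative activation by IL-4 and IL-13, 2 rose (adjusted p = 0.000813, and 0.0132 with an estimated correlation), and adjusted over the list alone 5 were higher and 1 was lower. Of 30 xenobiotic metabolism genes Fmo1 fell and 5 did adjusted over the list alone (adjusted p = 2.14e-07, and 0.0397 with an estimated correlation). Of 16 eosinophil, basophil and mast cell genes Mcpt2 rose, 2 adjusted over the list alone (adjusted p = 0.0163, and adjusted p = 0.109 with an estimated correlation), and of 20 macrophage genes none passed, 1 adjusted over the list alone (adjusted p = 0.0515). Of 15 MHC class II genes none passed, 1 adjusted over the list alone, with a median of 0.69 (adjusted p = 3.77e-05, and adjusted p = 0.24 with an estimated correlation). Atp2a1 rose by 2.36 ± 0.27, Nadsyn1 by 2.14 ± 0.27, Scin by 2.01 ± 0.23 and Slc26a4 by 1.66 ± 0.28. Il13 did not pass at -0.23 ± 0.21. Without centring 15 probes passed, and without OVA replicate 31 or PBS replicates 23 or 24 there were 25, 26 and 17. A fit of only the 2 groups gave 0, no reference block 19, scaling 66 and the omission of reference preparation 1.3 gave 25.

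Stat6-/- IL-13 perfusate was also set against PBS perfusate. Genotypes of the PBS and OVA animals are not given in the sources used here, so IL-13 and genotype cannot be told apart in this comparison. As 3 of the 5 Stat6-/- arrays had low Y-linked signal, a possible sex difference overlaps in part with the groups. Fits with these arrays marked or left out are given below. Il13 rose by 2.72 ± 0.21 (6.60-fold, adjusted p = 1.94e-06). The heat shock proteins Hsph1, Hspe1 and Dnaja1 rose by 1.76 ± 0.22, 1.55 ± 0.19 and 1.21 ± 0.26, and the lipid droplet protein Plin2 by 0.94 ± 0.17. Arl2bp was lower at -2.24 ± 0.31, the laminin chain Lamb1 at -1.86 ± 0.30, the lipid desaturase Scd2 at -1.49 ± 0.18, the transferrin receptor Tfrc at -1.45 ± 0.25 and the Y-linked gene Uty at -1.04 ± 0.21. The ciliated cell gene Ccdc39 was also lower, at -1.18 ± 0.20 (adjusted p = 0.0152). Clca1 and Muc5ac did not pass, at -0.91 ± 0.31 (adjusted p = 0.143) and -0.76 ± 0.32 (4 PBS arrays, adjusted p = 0.206). In all 101 of 16873 probes passed, 51 higher and 50 lower.

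Of 17 club cell genes 2 rose, Cyp2b10 by 0.92 ± 0.18 and Nupr1 by 0.80 ± 0.15, 2 also adjusted over the list alone (adjusted p = 0.0107, and adjusted p = 0.751 with an estimated correlation). Of 21 ribosomal protein genes none passed over all probes, and adjusted over the list alone 5 were higher and 1 was lower (adjusted p = 0.0107, and adjusted p = 0.751 with an estimated correlation). Of 30 xenobiotic metabolism genes 1 rose, and adjusted over the list alone 2 were higher and 1 lower (adjusted p = 0.0363, and adjusted p = 0.751 with an estimated correlation). Without centring 4 probes passed, 0 in a fit of only the 2 groups, 16 without a reference block, 255 after scaling and 270 after quantile normalization, the last with 181 higher and 89 lower. Leaving out single arrays gave 547 without Stat6-/- replicate 12, 202 without PBS replicate 25, 47, 21, 25 and 20 without Stat6-/- replicates 11, 10, 13 and 14, and 12, 22 and 15 without PBS replicates 22, 23 and 24. With the low Y-linked arrays marked by a covariate 7 passed, 24 without them (6 higher and 18 lower), and 13 without reference preparation 1.3.

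In whole lung, Stat6+/- was likewise compared with Stat6-/- among IL-13 animals. Clca1 rose by 7.58 ± 0.61 (adjusted p = 1.53e-05), Slc26a4 by 6.82 ± 0.83, Agr2, which folds mucins, by 4.67 ± 0.25, the lectin Itln1 by 4.77 ± 0.79 and Muc5ac by 3.87 ± 0.49. Members of the protease, alternative activation and macrophage lists rose as well, with the elastase Mmp12 at 6.85 ± 1.08, Arg1 at 6.28 ± 0.77 (4 Stat6+/- arrays), cathepsin Ctsk at 4.82 ± 0.37, Retnla at 4.92 ± 0.76 and Gpnmb at 4.65 ± 0.42. Chemokines rose too, among them Ccl3 by 4.30 ± 0.87, Ccl2 by 4.04 ± 0.46, Ccl6 by 3.50 ± 0.23, and with 4 Stat6+/- arrays Cxcl1 by 3.42 ± 0.43 and Ccl11 by 3.24 ± 0.32. Among the falls were Pon1 at -3.57 ± 0.22, Scgb3a2 at -3.19 ± 0.45 (4 Stat6+/- arrays) and Bpifa1 at -3.02 ± 0.47. In all 779 of 16096 probes passed, 520 higher and 259 lower. The array medians of these groups differed by -0.37, and without centring 284 passed and the split turned to 102 higher and 182 lower. After scaling 456 passed.

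Of 19 macrophage genes 15 rose, 17 adjusted over the list alone, including Clec7a at 3.61 ± 0.30, Itgax at 3.16 ± 0.27 and Cd68 at 3.12 ± 0.32 (adjusted p = 6.97e-36, and 0.026 with an estimated correlation). Of 20 genes of alternative activation 12 rose, 15 adjusted over the list alone, including Rnase2a at 5.04 ± 0.73 and the chitinase Chia1 at 4.34 ± 0.29 (adjusted p = 7.59e-20, and 0.00455 with an estimated correlation). Of 26 chemokines 10 rose and 1 fell, 13 and 1 adjusted over the list alone (adjusted p = 2.3e-16, and 0.02 with an estimated correlation). Of 27 proteases and antiproteases 12 rose, and adjusted over the list alone 16 were higher and 2 lower, with Mmp19 at 2.94 ± 0.35 and Serpina3n at 2.93 ± 0.51 (adjusted p = 2.07e-18, and 0.0185 with an estimated correlation). Of 26 endoplasmic reticulum genes 11 rose, 15 adjusted over the list alone, including the chaperone Hspa5 at 1.51 ± 0.19 (4 Stat6+/- arrays) and Creld2 at 1.28 ± 0.25 (adjusted p = 1.1e-11, and 0.0185 with an estimated correlation). Of 20 mucous cell genes 8 rose, 12 adjusted over the list alone (adjusted p = 1.62e-19, and 0.00532 with an estimated correlation). Of 23 extracellular matrix and fibrosis genes 2 rose, and adjusted over the list alone 4 were higher and 1 lower, and the list did not pass (adjusted p = 0.0733).

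Of 22 host defence genes 10 rose and 2 fell, 12 and 2 adjusted over the list alone, with Saa3 at 6.45 ± 0.45 (4 Stat6+/- arrays), the immunoglobulin receptor Pigr at 3.72 ± 0.21 and the alarmin Il33 at 3.37 ± 0.30 (adjusted p = 6.89e-16, and adjusted p = 0.0659 with an estimated correlation). Of 13 MHC class II genes 5 rose, 7 adjusted over the list alone, among them Ctss at 2.55 ± 0.29 and Cd74 at 1.24 ± 0.23 (adjusted p = 1.34e-08, and adjusted p = 0.121 with an estimated correlation). Of 12 neutrophil genes 2 rose, 5 adjusted over the list alone, lactoferrin Ltf by 2.89 ± 0.39 and the chemokine receptor Cxcr2 by 1.61 ± 0.33 for the first count (adjusted p = 0.00123, and adjusted p = 0.113 with an estimated correlation). Of 20 endothelial genes 5 fell, 10 adjusted over the list alone, including Eng at -1.55 ± 0.24 and the angiopoietin receptor Tek at -1.35 ± 0.22 (adjusted p = 7.86e-06, and adjusted p = 0.14 with an estimated correlation). Of 17 club cell genes 5 fell and 1, the lung collectin Sftpd, rose by 1.63 ± 0.25, and adjusted over the list alone 6 were lower and 3 higher (adjusted p = 0.000117, and adjusted p = 0.342 with an estimated correlation). Of 15 alveolar genes 3 fell and 1 rose, Cav1 being lower at -1.21 ± 0.20 and Sftpa1 higher at 0.90 ± 0.21, and 6 and 1 did adjusted over the list alone (adjusted p = 0.0194, and adjusted p = 0.268 with an estimated correlation). Of 22 immediate early and heat shock genes 4 rose, Hspa1a by 2.10 ± 0.39, Egr2 by 1.94 ± 0.35, Atf3 by 1.93 ± 0.44 and Junb by 1.42 ± 0.28, 5 adjusted over the list alone (adjusted p = 0.00123, and adjusted p = 0.281 with an estimated correlation). Il13 differed by 0.16 ± 0.36, Scgb1a1 by -0.01 ± 0.33 and Foxj1 by 0.10 ± 0.27, none of which passed. Stat6+/- arrays had a wider spread of log ratios, with a median absolute deviation of 1.03 ± 0.263 (SD, n = 5) against 0.688 ± 0.147 in Stat6-/- arrays.

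The reference pool was a block in this fit, and within pool 3 alone 21 probes passed and within pool 4 alone 82, while no block gave 391, a fit of only the 2 groups 400 and the replicate number as a block 0. The counts without Stat6-/- replicates 1, 4 or 6 were 499, 482 and 470, and with the low Y-linked arrays marked by a covariate or left out they were 309 and 204.

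Adding Epi+ to Stat6-/- animals changed 12 of 16096 whole lung probes, all 12 higher and each with 1 named gene. They were Clca1 by 6.56 ± 0.62 (adjusted p = 0.000449), Slc26a4 by 5.41 ± 0.85, Itln1 by 5.03 ± 0.80, Nadsyn1 by 3.57 ± 0.41, Agr2 by 3.38 ± 0.25, Chia1 by 3.10 ± 0.29, the protease Corin by 3.09 ± 0.38, Atp2a1 by 2.73 ± 0.39, the mucin Muc5b by 2.05 ± 0.33, Tff2 by 2.01 ± 0.26, the antibacterial lectin Reg3g by 1.97 ± 0.20 and the potassium channel Kcnj15 by 1.57 ± 0.24. Of 20 mucous cell genes 5 rose, 7 adjusted over the list alone (adjusted p = 2.08e-30, and 0.000359 with an estimated correlation). Of 20 genes of alternative activation Chia1 rose, and 2 did adjusted over the list alone (adjusted p = 4.05e-06, and 0.0339 with an estimated correlation). Of 22 host defence genes Reg3g rose, and adjusted over the list alone 4 were higher and 2 lower (adjusted p = 6.74e-06, and adjusted p = 0.167 with an estimated correlation). Muc5ac did not pass at 2.61 ± 0.49 (adjusted p = 0.141), nor did Arg1 at 1.40 ± 0.80 (4 Epi+ arrays) or Ccl11 at 0.18 ± 0.31. An unadjusted p under 0.05 was reached by 672 probes. Within reference pool 3 or pool 4 alone, or with the replicate number as a block, 0 probes passed, without centring 6 did, and 7 did without Epi+ replicate 6, Stat6-/- replicate 2 or Stat6-/- replicate 4. With the low Y-linked arrays marked by a covariate 6 passed, and 4 without them.

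Stat6+/- against Epi+ whole lung asked where lungs with Stat6+/- and lungs with Epi+ differed. Members of the protease, host defence, alternative activation, macrophage and chemokine lists were higher in Stat6+/- lung, Mmp12 by 7.70 ± 1.09, Saa3 by 6.62 ± 0.45 (adjusted p = 3.12e-05), Arg1 by 4.88 ± 0.82 (4 arrays per group), Gpnmb by 4.62 ± 0.43, Ctsk by 4.53 ± 0.38, Ccl2 by 3.58 ± 0.47, Ccl6 by 3.23 ± 0.24 and Ccl11 by 3.06 ± 0.32. Saa3 and Ccl11 had values on 4 Stat6+/- arrays. The mucous genes Clca1 and Muc5ac did not pass, at 1.03 ± 0.62 (adjusted p = 0.397) and 1.26 ± 0.49 (adjusted p = 0.183), while Agr2 was higher by 1.29 ± 0.25 and Tff2 by 1.81 ± 0.26. Pon1 was lower at -2.56 ± 0.22, the heart and muscle gene Popdc2 at -2.17 ± 0.19 and Eng at -1.45 ± 0.24. In all 550 of 16096 probes passed, 386 higher and 164 lower.

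Of 19 macrophage genes 13 were higher, 17 adjusted over the list alone (adjusted p = 1.17e-34, and 0.0448 with an estimated correlation). Of 26 endoplasmic reticulum genes 12 were higher, 18 adjusted over the list alone, such as Creld2 by 1.67 ± 0.26 and Hspa5, with 4 Stat6+/- arrays, by 1.51 ± 0.19 (adjusted p = 2.89e-14, and 0.025 with an estimated correlation). Of 20 alternative activation genes 7 were higher, 14 adjusted over the list alone, including the receptors Clec10a by 2.17 ± 0.24 and Mrc1 by 1.90 ± 0.32 (adjusted p = 9.83e-11, and 0.025 with an estimated correlation). Of 26 chemokines 8 were higher and 1 lower, 15 and 1 adjusted over the list alone (adjusted p = 2.89e-14, and 0.0448 with an estimated correlation). Of 27 proteases and antiproteases 13 were higher, and adjusted over the list alone 16 higher and 3 lower (adjusted p = 1.3e-15, and 0.0441 with an estimated correlation). Of 20 mucous cell genes 3 were higher, 6 adjusted over the list alone (adjusted p = 0.00695, and adjusted p = 0.204 with an estimated correlation). Of 23 extracellular matrix and fibrosis genes 2 were higher, and adjusted over the list alone 7 higher and 2 lower, and the list did not pass (adjusted p = 0.0659). Of 20 endothelial genes 4 were lower, Eng, Kdr at -1.24 ± 0.28, Tek at -1.15 ± 0.23 and Plvap at -0.97 ± 0.20, and 6 adjusted over the list alone (adjusted p = 6.88e-06, and adjusted p = 0.168 with an estimated correlation). Of 22 immediate early and heat shock genes 4 were higher, Hspa1a by 3.11 ± 0.40, Atf3 by 1.93 ± 0.45, Hsph1 by 1.73 ± 0.34 and Junb by 1.41 ± 0.28, 8 adjusted over the list alone (adjusted p = 6.81e-05, and adjusted p = 0.221 with an estimated correlation). Stat6+/- arrays had a median absolute deviation of 1.03 ± 0.263 (SD, n = 5) against 0.727 ± 0.202 in Epi+ arrays, and after scaling 218 probes passed. Without centring 77 probes passed, within reference pool 3 there were 8 and within pool 4 there were 0. Array weights gave 333, quantile normalization 271, no reference block 282, a fit of only the 2 groups 109 and the replicate number as a block 0. Without Epi+ replicates 3, 4 or 6 the counts were 273, 338 and 320, and without Stat6+/- replicates 3 or 5 they were 363 and 362.

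Ovalbumin against PBS in whole lung was measured on a platform of its own. Clca1 rose by 6.13 ± 0.47 (adjusted p = 0.000502), Arg1 by 5.66 ± 0.57 (4 arrays per group), the chemokine Ccl8 by 4.55 ± 0.34, Muc5ac by 4.00 ± 0.57, Mmp12 by 3.72 ± 0.61 and the basophil protease Mcpt8 by 3.77 ± 0.48 (4 OVA and 3 PBS arrays). Genes of dividing cells rose, Cdk1 by 2.45 ± 0.43 and Mki67 by 2.21 ± 0.39, as did B cell genes, Pou2af1 by 3.10 ± 0.62 and Ms4a1 by 2.02 ± 0.36, and interferon-inducible genes, Cxcl9 by 3.38 ± 0.30 and Cxcl10 by 1.73 ± 0.25. The dipeptidase Dpep1 was lower at -2.60 ± 0.38, Pon1 at -2.29 ± 0.39 and the lipase-binding protein Gpihbp1 at -1.65 ± 0.32. In all 299 of 17047 probes passed, 256 higher and 43 lower.

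Of 21 macrophage genes 11 rose, 18 adjusted over the list alone, such as the complement genes C1qb by 2.77 ± 0.41 and C1qc by 2.51 ± 0.35 (adjusted p = 1.31e-23, and 0.0146 with an estimated correlation). Of 26 chemokines 10 rose, 16 adjusted over the list alone (adjusted p = 2.07e-23, and 0.00946 with an estimated correlation). Of 27 cell cycle genes 9 rose, 20 adjusted over the list alone (adjusted p = 1.5e-20, and 0.0141 with an estimated correlation). Of 25 interferon response genes 6 rose, 13 adjusted over the list alone (adjusted p = 1.4e-11, and 0.00815 with an estimated correlation). Of 15 B and plasma cell genes 3 rose, 12 adjusted over the list alone (adjusted p = 9.97e-12, and 0.0295 with an estimated correlation). Of 15 MHC class II genes 2 rose, 12 adjusted over the list alone (adjusted p = 6.56e-12, and 0.00976 with an estimated correlation). Of 20 eicosanoid genes 3 rose, 9 adjusted over the list alone, with Tbxas1 at 2.65 ± 0.37 and Alox15 at 2.62 ± 0.37 (adjusted p = 3.39e-07, and 0.015 with an estimated correlation). Of 21 endothelial genes none passed over all probes and 11 were lower when adjusted over the list alone (adjusted p = 6.75e-08, and 0.00815 with an estimated correlation). Of 22 mucous cell genes 6 rose, 8 adjusted over the list alone (adjusted p = 1.38e-10, and 0.00976 with an estimated correlation). Of 19 alternative activation genes 7 rose, 13 adjusted over the list alone (adjusted p = 1.1e-16, and 0.0221 with an estimated correlation). Of 17 T cell genes none passed over all probes and 7 were higher when adjusted over the list alone (adjusted p = 3.39e-07, and adjusted p = 0.0517 with an estimated correlation). Of 16 eosinophil, basophil and mast cell genes 2 rose, and adjusted over the list alone 9 were higher and 1 lower (adjusted p = 1.78e-05, and adjusted p = 0.0656 with an estimated correlation). Ccl11 rose by 1.51 ± 0.22, while Il13 did not pass at 0.73 ± 0.36 (adjusted p = 0.351). Without centring 36 probes passed, 35 higher and 1 lower, and after quantile normalization 258 did, 180 higher and 78 lower, while array weights gave 796, 567 higher and 229 lower, and the replicate number as a block gave 4. Without OVA replicate 1 or PBS replicates 2, 3, 4 or 5 the counts were 109, 105, 179, 117 and 115.

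The IL-13 comparisons of both tissues were then set against each other by an interaction term, perfusate minus whole lung. For Stat6+/- against Stat6-/-, the difference was -6.74 ± 0.71 for Arg1 (adjusted p = 3.13e-07), -6.45 ± 1.08 for Mmp12, -6.01 ± 0.79 for Saa3, -5.87 ± 0.72 for Cxcl1, -4.83 ± 0.57 for Gpnmb, -4.59 ± 0.30 for Agr2 and -3.82 ± 0.66 for Clca1. The effect on Muc5ac differed by -0.50 ± 0.56, which did not pass. Differences above 0 included Bpifa1 at 2.73 ± 0.48, Scgb3a2 at 2.58 ± 0.48, Pon1 at 1.82 ± 0.28 and Eng at 1.51 ± 0.37, genes that fell in whole lung. Of 15370 probes 662 passed, 192 above and 470 below 0. Without centring 373 passed and the split turned to 270 above and 103 below. Scaling gave 305, quantile normalization 374 and no reference block 350, and without the low Y-linked arrays 238 passed, 64 above and 174 below.

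Of 19 macrophage genes 14 were below 0, 16 adjusted over the list alone (adjusted p = 3.14e-29, and 0.00185 with an estimated correlation). Of 19 alternative activation genes 11 were below 0, and adjusted over the list alone 14 were below and 1 above (adjusted p = 4.22e-16, and 0.000401 with an estimated correlation). Of 20 mucous cell genes 6 were below 0, and adjusted over the list alone 8 were below and 1 above (adjusted p = 7.92e-07, and 0.00249 with an estimated correlation). Of 25 chemokines 10 were below 0, and adjusted over the list alone 14 were below and 1 above (adjusted p = 1.46e-12, and adjusted p = 0.0687 with an estimated correlation). Of 19 endothelial genes 3 were above 0, and adjusted over the list alone 6 were above and 1 below (adjusted p = 0.000759, and 0.0219 with an estimated correlation). For Epi+ against Stat6-/- the tissues differed at 15 of 15370 probes, 2 above and 13 below 0. They included Agr2 at -3.23 ± 0.30, Chia1 at -2.70 ± 0.37, Cxcl1 at -3.80 ± 0.70, Sftpa1 at -2.12 ± 0.33, Muc5b at -1.92 ± 0.35 and Pigr at -1.71 ± 0.35, while Clca1 did not pass at -2.81 ± 0.67 (adjusted p = 0.135). Of 22 host defence genes 3 were below 0, and adjusted over the list alone 5 were below and 1 above (adjusted p = 6.74e-09, and 0.00286 with an estimated correlation). Of 20 mucous cell genes 2 were below 0, and adjusted over the list alone 5 were below and 1 above (adjusted p = 2.6e-07, and 0.000534 with an estimated correlation). Without centring 5 passed, 0 above and 5 below, after scaling 9 did, 0 above and 9 below, quantile normalization gave 7, no reference block 5, probes with a value on every array 9 and at least 2 arrays per group 23, and without Stat6-/- perfusate replicate 14 or Epi+ whole lung replicate 6 there were 9 and 8. By the labels whole lung RNA was not amplified and perfusate RNA was, except that 3 perfusate labels do not state it, so tissue and preparation cannot be told apart in these differences.

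The overlap of the changes of Stat6+/- against Stat6-/- in IL-13 animals with those of ovalbumin was counted within each tissue. In perfusate 13 probes rose in both, where independent lists would share 0.323, among them Clca1, Muc5ac, Slc26a4, Atp2a1, Nadsyn1, Scin and Flvcr1, and 5 fell in both, against 0.222, namely Hp, Ccn2, Fmo1, Epdr1 and Cpsf2. In whole lung 76 of the probes on both platforms rose in both, against 7.88, among them Clca1, Agr2, Arg1, Mmp12, Saa3, Retnla, Ccl2, Ccl8, Ccl11, Cd68, the C1q genes and Muc5b, and 13 fell in both, against 0.663, among them Pon1, Cav1, Fmo2 and Aldh3a1. No probe was called in opposite directions in either tissue. Across probes Pearson's r was 0.197 in perfusate and 0.242 in whole lung. These comparisons share no control arrays. Without centring 8 and 16 probes were shared in direction. The perfusate count was 10 without a reference block, 11 without OVA replicate 31 and 7 without PBS replicate 24, and the whole lung count was 47, 48, 59, 47 and 47 without OVA replicate 1 and PBS replicates 2, 3, 4 and 5.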

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

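The tests for an exchange of labels, for a lower share of resident cells, for gene lists after the exchange and for other splits of the arrays were chosen after the results were seen, while the other tests of this part were written before.

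Within groups of 5 arrays, a value was marked when its gap to the nearest other array was a large part of the range of the group. Such marks arise by chance in about 1 in 20 groups, and 6 of 110 tests gave one. Ccl11 stood at -1.32 on perfusate PBS replicate 24 against -0.29 to -0.10 on the other arrays of the group, and 12.5% of the spots of that array had no value against 4.20% to 5.23%. Whole lung OVA replicate 5 had Il13 at 2.57 against 0.68 to 1.14, and a median absolute deviation of log ratios of 1.57 against 0.753 to 0.912. Stat6 was -0.18 on whole lung PBS replicate 2 against 0.26 to 0.38. On whole lung Stat6-/- replicate 4, 3.62% of the spots had no value against 6.96% to 7.34%.

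Differences between the tissues were marked by the interaction term of limma. The effect of Stat6+/- against Stat6-/- differed at 662 probes, with Clca1 at -3.82, Arg1 at -6.74 and Ccl11 at -2.94, perfusate minus whole lung, and the effect of Epi+ differed at 15 probes. By the labels, perfusate RNA was amplified (3 labels do not state it) and whole lung RNA was not, so amplification cannot be separated from tissue in these differences.

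The first pattern weighed was low Y-linked signal on 3 perfusate and 2 whole lung arrays, all of Stat6-/- groups, which in perfusate was read from 1 of 2 Eif2s3y spots (the other read 0.52, 0.17 and 0.03). With a covariate for these arrays, the log2 differences of the probes called for Stat6+/- against Stat6-/- had a median ratio to the original ones of 1.03 in perfusate (528 probes, quartiles 0.915 and 1.14) and 0.998 in whole lung (779 probes, quartiles 0.943 and 1.05). This argues against a sex difference as the source of these calls, for which the ratio would fall below 0.3. The probes had been called on the same arrays, which favours probes on which the Stat6-/- arrays agree, so the ratio may lean towards 1. In perfusate the covariate itself called 0 probes, and Eif2s3y had a limma adjusted p of 0.215 for it. The calls fell to 163 and 309, while standard errors grew by median factors of 1.42 and 1.20. Xist was higher on the same 3 perfusate arrays (-0.33 to 0.91, with -5.70 to -1.36 on the others) and stood at 7.35 on 1 of the 2 whole lung arrays, as a difference in sex would give, but the sources used here do not give the sex, so it stays open.

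The second pattern was the rise of macrophage genes in Stat6+/- whole lung, whose arrays had a wider spread. After scaling all arrays to one spread, 10 of 19 macrophage genes were called higher, against 15 before. This count argues against the spread as the whole source, but only just, since 10 was the lowest number set for that reading. The list had an adjusted p of 3.1e-33 after scaling, with the preset inter-gene correlation. That list test cannot decide on the spread, because it compares the list with other probes of the same arrays, which scaling changes alike. A lower share of resident cells stays open, since 3 forms of the test did not all give the same answer: the highest of the medians of 6 resident cell lists exceeded the lowest by 1.05 with a standard error of 0.42, the medians differed with a permutation p of 0.0316, and Cochran's Q was 8.56 (p = 0.128). The form was changed after the first was run and again after the second, in this order, and the medians were -0.02 for ciliated, -0.40 for club, 0.48 for basal, -0.43 for alveolar, -0.56 for endothelial and -0.16 for smooth muscle genes. More macrophages, or a change within them, is an untested biological hypothesis.

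The third pattern was that exchanging Stat6-/- replicate 12 and PBS replicate 25 of perfusate raised the calls from 133 to 1967, in a split that crosses reference preparations. Il13 was 3.41 on the former, with 2.06 to 3.17 on the other Stat6-/- arrays, and -0.37 on the latter, with -0.22 to 0.48 on the other PBS arrays, which argues against swapped labels. An array-wide technical axis stays open, since over 25 arrays the leading component of the residuals (21.5% of their variance) had an absolute r of 0.643 with the deposited array median (permutation p = 0.00055), a rank correlation of 0.630 (permutation p = 0.001), and an r of 0.637 without the 2 arrays farthest from the median. Both measures were residuals of the fit, which the shuffling treats as independent values, so these permutation p-values are likely too small. After the exchange 1 of 30 gene lists passed, that of club and secretory cells (17 genes, median 0.37 higher, adjusted p = 0.0258), but no group of the design accounts for it, and no biological explanation was tested.

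The calls were also counted over 100 splits of the arrays of each comparison, the real split included, on probes with a value on every array. In perfusate, as many calls came from 1 split for Stat6+/- against Stat6-/- (580 real, 43 highest other), 1 for Epi+ against Stat6-/- (106 and 11), 1 for Stat6+/- against Epi+ (7 and 1), 3 for OVA against PBS (39 and 1011) and 3 for Stat6-/- against PBS (133 and 1967). In whole lung it was 1 split for Stat6+/- against Stat6-/- (953 and 0), 1 for Epi+ against Stat6-/- (15 and 0), 1 for Stat6+/- against Epi+ (825 and 233) and 1 for OVA against PBS (440 and 1). For the tissue differences it was 1 for Stat6+/- (586 and 481) and 2 for Epi+ (9 and 17). When only splits that keep each reference pool balanced as it was are counted, 1 of 60, 1 of 100 and 1 of 100 gave as many for the IL-13 comparisons of whole lung in the order above (highest others 0, 0 and 233). These shares lie under 0.05, as does that of OVA against PBS in whole lung, which had 1 pool. They were not adjusted for the number of comparisons. The splits treat arrays as separate samples, which the labels do not state, so they cannot exclude chance differences between animals. For the tissue differences 2 of 100 (highest other 666) and 3 of 100 (highest other 15) gave as many calls. Only 100 of 1920 and of 3200 such splits were drawn, and 1 or more of them gave more calls than the real ones. These splits mix groups in both tissues at once, so an effect in 1 tissue alone could set the real split apart. They therefore cannot decide whether chance accounts for a difference between the tissues. In perfusate each reference preparation holds 1 array of every group, and only 16 splits keep that, too few for a share under 0.05. The highest others among them were 3, 11, 0, 2 and 1, in the order above. The split with 1011 calls set reference preparations 1.2 and 1.3 against 1.1 and 1.5, with arrays of 1.4 on both sides. Both this split and the real one, with 39 calls, were fitted with these preparations as a block. The splits with 1011 and 1967 calls point to a structure of the perfusate arrays beyond the groups.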

How the results depend on the processing

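The alternatives chosen after the data were seen were the values as deposited, each spot on its own, probes with 1 symbol, scaling and quantile normalization for the gene lists, the omission of reference preparation 1.3, probes picked without the controls of the Epi+ side, and the covariate for, or omission of, the arrays with low Y-linked signal. No named gene or gene list that passed, before or under an alternative, changed direction. The majority of calls did turn. As deposited it went to 102 higher and 182 lower for Stat6+/- against Stat6-/- in whole lung, 270 above and 103 below for that tissue difference, and 11 higher and 6 lower for Epi+ against Stat6-/- in perfusate. The last also turned with the Y-linked covariate (13 and 9), without those arrays (20 and 14) and in the fit of 2 groups (1 and 0). Stat6+/- against Epi+ in perfusate turned without reference preparation 1.3 (2 and 3). For Stat6-/- against PBS, 51 and 50 before, falls led with at least 2 arrays per group (49 and 50), array weights (65 and 74), without the low Y-linked arrays (6 and 18), and without Stat6-/- replicates 11 (21 and 26) or 12 (251 and 296) or PBS replicate 24 (7 and 8). Counts within 1.5 times the original are not listed, and where a count moved further the cause was not tested unless named. Testing each spot on its own moved no count that far. Spot intensities were not used, so signal over background could not be set as a limit. Below, A stands for Stat6+/- against Stat6-/-, B for Epi+ against Stat6-/-, C for Stat6+/- against Epi+, D for OVA against PBS and E for Stat6-/- against PBS. Counts of calls are those of limma. Some alternatives gave 0 calls, and the unadjusted counts of those fits are not given here. In the main fits of the same comparisons, the numbers of probes with an unadjusted limma p under 0.05 were 1184 (perfusate C), 1545 (perfusate D), 3289 (perfusate E), 3081 (whole lung A), 672 (whole lung B) and 3063 (whole lung C).

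As deposited, perfusate gave 128 (A), 17 (B), 0 (C), 15 (D) and 4 (E), whole lung 284 (A), 6 (B), 77 (C) and 36 (D), the tissue differences 373 (A) and 5 (B), and the overlap with OVA 8 in perfusate and 16 in whole lung. Scaling gave 50 (B), 0 (C), 66 (D) and 255 (E) in perfusate, 456 (A) and 218 (C) in whole lung, and 305 (A) and 9 (B) for the tissue differences. Quantile normalization gave 51 (B), 0 (C) and 270 (E) in perfusate, 271 (C) in whole lung, and 374 (A) and 7 (B) for the tissue differences.

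Probes with a value on every array gave 7 for perfusate C and 9 for tissue difference B. At least 2 arrays per compared group gave 2 and 23 for them. For perfusate C the robust variance model and probes with 1 symbol gave 2 each. Array weights gave 989 (A), 170 (B) and 261 (C) in perfusate, and 333 (C) and 796 (D) in whole lung. No reference block gave 270 (A), 31 (B), 2 (C), 19 (D) and 16 (E) in perfusate, 391 (A) and 282 (C) in whole lung, 350 (A) and 5 (B) for the tissue differences, and 10 for the overlap with OVA in perfusate. Fits of only the 2 groups, which have fewer arrays, gave 69 (A), 1 (B), 0 (C), 0 (D) and 0 (E) in perfusate, and 400 (A) and 109 (C) in whole lung.

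The Y-linked covariate gave 163 (A), 22 (B) and 7 (E) in perfusate, and 309 (A) and 6 (B) in whole lung. Omission of those arrays gave 175 (A), 34 (B) and 24 (E) in perfusate, 204 (A) and 4 (B) in whole lung, and 238 for tissue difference A. Without reference preparation 1.3 perfusate gave 35 (B), 25 (D) and 13 (E). Within reference pool 3, whole lung gave 21 (A), 0 (B) and 8 (C), and within pool 4 it gave 82 (A), 0 (B) and 0 (C). The replicate number as a block gave 0 (A), 0 (B), 0 (C) and 4 (D) in whole lung. These fits kept only arrays whose number occurred in both groups, so they held fewer arrays. Of 16 pairs of equal number, 5 correlated above 0.1 (range -0.596 to 0.364). In the IL-13 groups, pairs of the same reference pool lay at 0.0642 to 0.364 and pairs of different pools at -0.596 to -0.172. The pool was not removed before this check, so it cannot decide whether equal numbers mark similar arrays. With the correlation estimated, on probes with a value on every array of the fit, 34 gene lists passed instead of 102.

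With each array left out in turn, perfusate counts ranged from 347 to 539 (A), 42 to 92 (B), 0 to 18 (C), 17 to 34 (D) and 12 to 547 (E). Whole lung counts ranged from 470 to 1066 (A), 7 to 13 (B), 273 to 806 (C) and 105 to 308 (D), and the tissue differences from 502 to 919 (A) and 8 to 19 (B). The overlap with OVA ranged from 7 to 19 probes in perfusate (r 0.149 to 0.248) and 47 to 96 in whole lung (r 0.190 to 0.284), and the share of the Stat6 effect with Epi+ from 0.504 to 0.607 and 0.193 to 0.263. Over probes picked without the controls of the Epi+ side, that share was 0.352 in perfusate and 0.144 in whole lung.

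Of 270 gene list results, 252 kept direction and side of the threshold as deposited (11 newly passed, 7 no longer did), 249 after scaling (10 and 11), 252 after quantile normalization (10 and 8) and 202 with the estimated correlation (68 no longer passed). Named genes that no longer passed are counted next, with those that kept their side of the threshold in brackets. Not every alternative covered every comparison. The counts were 229 (295) as deposited, 146 (378) after scaling and 115 (409) after quantile normalization. They were 40 (481) with array weights, 29 (495) with at least 2 arrays, 10 (514) with the robust model and 120 (341) without the block. Fits of 2 groups gave 185 (169) and the replicate block 227 (24). Pool 3 alone gave 151 (34) and pool 4 alone 139 (42). The counts were 51 (113) without preparation 1.3, 149 (190) without the low Y-linked arrays, 98 (242) with their covariate and 1 (523) with 1 symbol. Over the fits with 1 array left out, where each named gene counts once per fit, the gene kept its side of the threshold 5313 times, no longer passed 968 times and newly passed 2 times.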

Other observations

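The overlaps in this part were counted after the results were seen, and the genes named here were chosen after their values were seen. Between perfusate and whole lung, the effects of Stat6+/- against Stat6-/- had a Pearson r of 0.122 over 15370 probes. Of the called probes 29 rose in both tissues, where independent lists would share 5.96, and 26 fell in both, against 5.35, while 16 went opposite ways, against 13.7. Those that rose in both included Clca1, Muc5ac, Muc5b, Muc4, Galnt7, Slc26a4, Atp2a1, Nadsyn1, Scin, Manf, Dnajb9, Car2 and Cldn2. Those that fell in both included Pon1, Gsta2, Fmo2, Aldh3a1, Cckar, Cyp4b1, Hpgd, Scnn1g and Selenbp1. For Epi+ against Stat6-/-, Atp2a1, Clca1, Nadsyn1 and Slc26a4 rose in both tissues, 4 probes against 0.0172 for independent lists. In perfusate, Epi+ and OVA shared 8 rises, namely Atp2a1, Clca1, Col6a4, Fkbp11, Muc5ac, Nadsyn1, Scin and Slc26a4, and 3 falls, Cpsf2, Epdr1 and Hp.

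Over 717 accessions with 2 spots, the spots differed by a median of 0.35 within an array, and 107 accessions had a correlation over 0.8 between their spots. Of the 2 spots of Eif2s3y, the one used followed Uty with a correlation of 0.795 and the other with 0.335. That spot and the minimum of -1.5 were chosen after the values were seen.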
